A study of Xenopus laevis with 9 samples.

How the data were processed

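Total RNA of frog pancreas was extracted with TRIZOL from pools of 5 to 10 tadpoles per replicate, labelled with Cy3 by linear amplification and hybridised with Cy5-labelled universal *Xenopus laevis* reference RNA, per the labels' protocols. The dyes were not swapped. The protocol text names pancreas and liver in the same sentence on pooling, while every sample label gives pancreas alone, and the samples are treated here as pancreas. The 3 pools of a stage are taken as separate samples because the labels call each pool a replicate. The labels name thyroid hormone as the agent for every sample and say that all parts of the study had the same hormone levels. The groups are labelled by stage, and no hormone level of the animals was available here. An effect of hormone level therefore cannot be told apart from stage, and no untreated group was analysed here. The 3 stages were compared pairwise, NF62 was compared with the mean of the other stages, and all 3 were compared by an F test.

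The deposited scanner files hold spot brightness as intensity values that are not background-subtracted or normalized, together with processed intensity values and a log10 ratio of red over green. Per the file headers, the arrays were extracted with Agilent Feature Extraction A.7.5.1 on 1 day, each array on a slide of its own, with local background subtraction and a dye normalization whose LOWESS smoothing factor was 0.25. The arrays were extracted in stage order, so run order and stage cannot be told apart, and no batch holding over 1 array could be tested. The deposited value table of the series is on a log10 scale. Within each array it correlated at 0.991 or more with the log processed pancreas signal. Its differences between arrays matched those of the log10 ratio with the sign turned, with a correlation of 0.995 and a slope of 0.999, which sets its direction as pancreas over reference. Its column medians were 2.92 to 2.93, and how the authors brought the ratio to that level is not given in the sources used here.

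Mean spot signals and median local backgrounds were corrected with the normexp method and an offset of 50 in limma 3.58.1 (R 4.3.3). Each array was then normalized by loess, with control spots and outlier-flagged spots at weight 0. The 1080 control spots were left out afterwards, and outlier-flagged values, 110 to 319 per array, were set to missing. An offset of 50 makes folds of dim probes smaller, and calls of at least 2-fold come mainly from brighter probes. Of the 1852 such probes between NF52 and NF62, 0 lie in the dimmest of 5 equal groups of probes, whose median pancreas signal is 35.4. The loess step assumes that at each brightness most probes do not change relative to the reference. The raw pancreas signal of the 1000 brightest probes had a median log2 level of 10.5 at NF52, 11.5 at NF62 and 11.4 at NF66, a difference that loess removes. Of the 456 probes called at least 2-fold lower at NF62, 402 were also lower in raw pancreas signal. Saturated spots were kept: 12 to 15 probes were saturated in the pancreas channel per NF52 array, 23 to 27 per NF62 array and 27 to 36 per NF66 array, and a probe saturated on all arrays of a stage is given with its smallest fold over the 27 settings that gave it a value, the main one among them, and the pancreas signal above background, which is not a bound for other methods. The pancreas channel alone after loess and Aquantile normalization, open to dye bias without dye swaps, gave higher folds, 197 for BX849304_822, 355 for BC053824_1058 and 35.5 for BC054271_1668.

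Log2 ratios were fitted with lmFit and eBayes in limma on all 9 arrays with 1 mean per stage, which gives 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The test, the samples and the alternatives were chosen before the data were examined. The planned filter kept probes that the scanner software called well above background on all 3 arrays of some stage. It removed no probe, because 99.98% or more of probes passed on every array. A filter at the 95th percentile of the negative control spots was therefore added after seeing the data. The procedure was tested on simulated data for NF62 against NF52 with 21495 probes and a known set of changed probes. It recovered 83.6% of changes of 0.5 log2 units, 94.0% of changes of 1 unit and 100% of changes of 2 units, with 17 false calls among 202. Of 36 array pairs, none had exactly the same pancreas signal for more than 0.0279% of probes.

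The rule for named items was the largest rises and falls past the threshold with no overlap between replicates of the 2 stages, 1 probe per accession. It was written for named genes. The file column for gene names holds sequence accessions, none matched a symbol, synonym or accession of the gene table, and therefore the rule was applied to probe identifiers, limited to 2 rises and 2 falls per comparison. A further condition, a value on all 6 arrays, was set after seeing the data. The 27 gene lists, with 885 symbols, could be matched to 0 probes, so their set tests were not run. Genome positions were not assigned because no genome was used here. In their place, 47 groups of conserved protein signatures were searched in the forward translations of the probes, written after the probe sequences but before the expression values were seen. Most probes lie in sequence without such a signature, and the 3 groups with at least 3 probes and no hit in the reverse or shuffled sequence were used (Biostrings 2.70.1). Sets were tested with fry and camera in limma.

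The alternatives were no background correction, an offset of 16, the scanner software's log ratio, its processed signals after median centring, median centring in place of loess, scale normalization between arrays, the pancreas channel alone after Aquantile or quantile normalization, and the deposited value table. Others were no filter, a filter in both channels, fits of 2 stages only, array weights, a trended robust eBayes, a replicate block and leaving out each array. Chosen after seeing the data were the negative control filter, keeping outlier-flagged spots and leaving out saturated spots. Figures were drawn with matplotlib 3.10.9.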

Results

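Gene expression was measured in the pancreas of *Xenopus laevis*, the African clawed frog, at 3 Nieuwkoop-Faber (NF) stages of development. NF52 is a tadpole stage before metamorphosis, NF62 falls at metamorphic climax, when the tadpole organs are rebuilt, and NF66 is the young frog at the end of metamorphosis. Thyroid hormone drives this change, and the stated aim of the series was to find genes whose expression differs between these stages in the pancreas. Each stage had 3 arrays, and each array carried RNA of 1 pool of 5 to 10 tadpoles. The pancreas RNA was labelled with the green dye Cy3 and hybridised with a universal frog reference RNA in the red dye Cy5, so each probe gives a log2 ratio of pancreas over reference. The 9 arrays carried 21495 probes of 60 bases. Median pancreas signal above local background was 81.9 to 108 brightness units on the NF52 arrays, 105 to 116 on the NF62 arrays and 109 to 198 on the NF66 arrays, against 64.8 to 86.5 for the reference, and the number of arrays limits the precision of every value below. The array files pair probes with sequence accessions and not with gene names, and 0 of the 21495 probes matched the gene table used here. Probes are therefore given by their identifiers and sequences. No member of the pancreatic, liver, blood and immune gene lists chosen beforehand could be matched to a probe, though the arrays may measure some of them.

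The arrays separated by stage. The first principal component held 58.1% of the variance and set NF62 apart from both other stages. The second held 29.8% and placed NF52 and NF66 at its opposite ends. Correlations between arrays of 1 stage were 0.978 to 0.982 at NF52, 0.928 to 0.984 at NF62 and 0.970 to 0.974 at NF66. NF52 and NF66 arrays correlated at 0.832 to 0.862. NF62 arrays correlated less with either, at 0.621 to 0.736 with NF52 and 0.700 to 0.818 with NF66. NF62 replicate 1 stood apart from the other NF62 arrays, with correlations of 0.928 and 0.929, while replicates 2 and 3 correlated at 0.984.

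**Figure D1:**
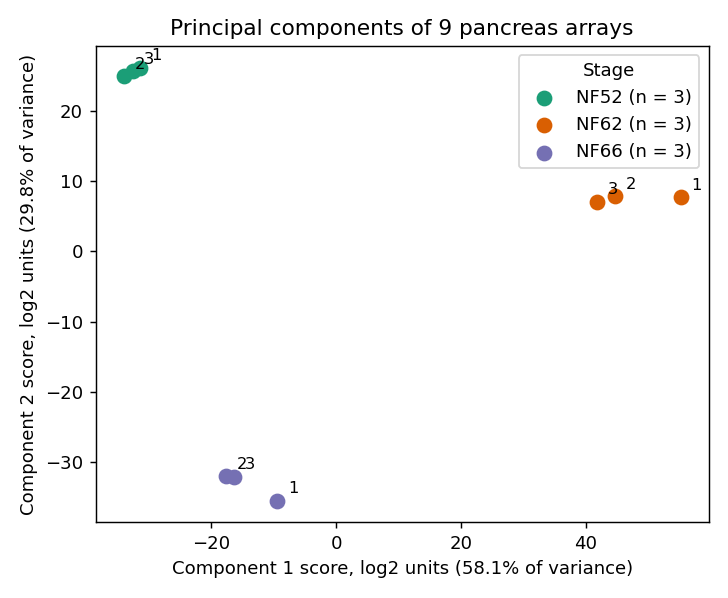
Scores of the 9 arrays on principal component 1 (x axis, 58.1% of variance) and component 2 (y axis, 29.8%), in log2 units, over 20533 probes; each point is 1 array, coloured by stage and numbered by replicate. The 3 NF62 arrays lie at component 1 scores of 41.8 to 55.2, and the NF52 and NF66 arrays all lie below 0 on that axis.

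From NF52 to NF62, into metamorphic climax, pancreas expression changed widely, and most changes of at least 2-fold were rises. At least 2-fold higher levels at NF62 were found for 1396 probes and at least 2-fold lower levels for 456, so that 75.4% of these changes were rises. Of these, 9 falls and 0 rises were saturated in the pancreas channel on all 6 arrays, so their pancreas signal was capped at both stages. Rises of at least 4-fold numbered 171, and falls of that size 81. Probe BX849304_822 (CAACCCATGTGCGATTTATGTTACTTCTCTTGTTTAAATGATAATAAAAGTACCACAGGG) rose from −1.12 ± 0.18 to 4.67 ± 0.10 on the log2 ratio scale (SD, n = 3 each; limma adjusted p = 9.24e-07). It was saturated on all 3 arrays at NF62 and stayed saturated at NF66, so its size is not measured in full. The rise was at least 37.3-fold over the 27 settings that gave a value and in pancreas signal above background. Probe U41855_2167 (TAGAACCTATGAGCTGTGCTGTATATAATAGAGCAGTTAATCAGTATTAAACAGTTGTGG) rose 53.4-fold, from −4.21 ± 0.17 to 1.53 ± 0.35 (limma adjusted p = 5.44e-07). Among the falls, probe BC048227_2453 (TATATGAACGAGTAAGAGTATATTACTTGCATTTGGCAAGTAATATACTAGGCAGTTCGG) was 16.3-fold lower, moving from 2.36 ± 0.21 to −1.67 ± 0.87 (limma adjusted p = 3.25e-05). Probe BC057715_2454 (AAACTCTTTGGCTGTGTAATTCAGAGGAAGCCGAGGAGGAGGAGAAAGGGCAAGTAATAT) was 14.6-fold lower, moving from 1.84 ± 0.19 to −2.04 ± 0.33 (limma adjusted p = 1.41e-05), and was still at −2.05 ± 0.73 at NF66. Over other settings that kept all arrays, the log2 changes were 4.21 to 6.14 for U41855_2167, −4.37 to −2.82 for BC048227_2453 and −4.20 to −2.84 for BC057715_2454.

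Without the fold limit, 11479 of 21419 probes differed between NF52 and NF62 at a limma adjusted p under 0.05, 5969 higher and 5510 lower at NF62. That is 52.0% higher, against 44.4% by the scanner software's log ratio, so the balance of small changes has no settled direction. The replicate values of the 2 stages did not overlap for 63.9% of probes with all 6 values, where chance gives 10%. Of the 1396 rises, 1330 kept their direction and their side of the threshold under each of 10 normalizations, as did 374 of the 456 falls, and 241 of these rises and 104 of these falls stayed at least 2-fold in all 10. The share of rises is less certain, since without background correction only 516 probes changed at least 2-fold, 49.6% of them higher, and with median centring in place of loess the share was 89.0%. The scanner software's own log ratio gave 2836 probes changed at least 2-fold, 64.8% of them higher.

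**Figure D2:**
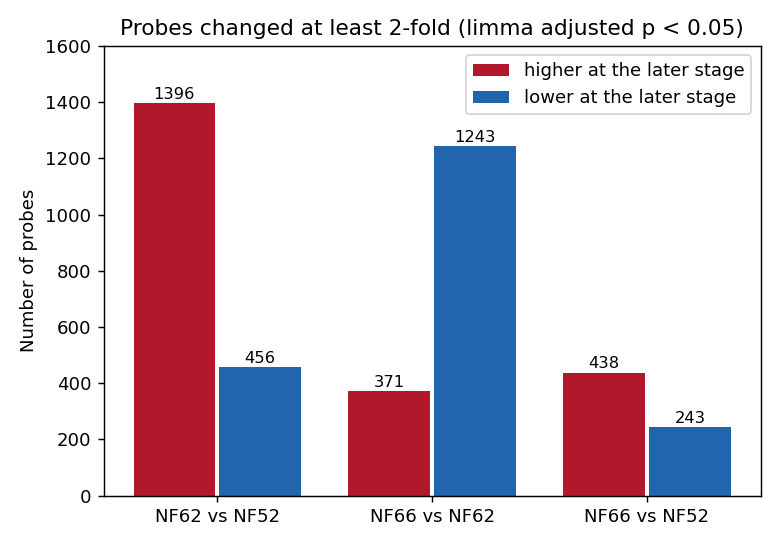
Number of probes (y axis) changed at least 2-fold between 2 stages with a limma adjusted p under 0.05, for the 3 comparisons on the x axis; red bars count probes higher at the later stage and blue bars probes lower at the later stage. Rises outnumber falls into NF62 (1396 against 456), and falls outnumber rises from NF62 to NF66 (1243 against 371).

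From NF62 to NF66, as metamorphosis was completed, the balance was the opposite, with 371 probes at least 2-fold higher and 1243 at least 2-fold lower at NF66. For 16 of these rises and 0 of these falls the pancreas channel was saturated on all 6 arrays, so the called change does not show in the capped pancreas signal. Probe AB002629_3212 (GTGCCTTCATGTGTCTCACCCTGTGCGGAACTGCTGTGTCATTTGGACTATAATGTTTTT) rose 26.4-fold, from −0.20 ± 0.08 at NF62 to 4.52 ± 0.33 at NF66 (SD, n = 3 each; limma adjusted p = 3.21e-07), after −0.48 ± 0.20 at NF52. Probe CD256819_1385 (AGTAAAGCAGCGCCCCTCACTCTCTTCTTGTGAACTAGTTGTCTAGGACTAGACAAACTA) rose 24.9-fold, from 0.65 ± 0.03 to 5.28 ± 0.26 (limma adjusted p = 2.39e-07). Probe U41855_2167, which had risen into NF62, fell 23.3-fold to −3.01 ± 0.35 at NF66 (limma adjusted p = 8.15e-07) and so came back towards its NF52 level. Probe BC053782_1123 (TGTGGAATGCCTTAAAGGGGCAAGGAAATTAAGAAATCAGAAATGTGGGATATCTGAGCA) was 22.7-fold lower, moving from 1.31 ± 1.37 to −3.20 ± 0.52 (limma adjusted p = 0.000264), with a wide spread at NF62 that came from replicate 1. Without that array its log2 change was −3.71 in place of −4.51. Over other settings that kept all arrays, the log2 changes were 3.79 to 4.96 for AB002629_3212, 3.80 to 4.88 for CD256819_1385, −4.77 to −3.97 for U41855_2167 and −4.71 to −3.47 for BC053782_1123. In all, 10111 probes differed between NF62 and NF66 (limma adjusted p under 0.05), 4438 higher and 5673 lower. Of the probes changed at least 2-fold, 312 of the 371 rises and 1183 of the 1243 falls held in direction and threshold under each of 10 normalizations, and 118 and 195 stayed at least 2-fold in all 10. The scanner software's own log ratio put 54.8% of all calls higher at NF66, against 43.9% here, so the balance of small changes has no settled direction, and without background correction 414 probes changed at least 2-fold, 43.2% of them higher.

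Many probes that changed into climax moved back out of it. Of the 1396 probes that rose at least 2-fold by NF62, 751 (53.8%) fell at least 2-fold by NF66. Their median log2 change was 1.40 into NF62 and −1.39 out of it, leaving 0.02 between NF66 and NF52, and 477 of them did not pass the test between NF52 and NF66. Of the 456 probes that fell by NF62, 145 (31.8%) rose at least 2-fold by NF66, with a median of −1.60 followed by 1.22. Only 10 probes rose at least 2-fold at both steps, and 3 fell at both. Independent lists of these sizes would share 81.1 probes for a rise then a fall and 7.90 for a fall then a rise. Both changes contain the NF62 level, with opposite sign, so an excess over independent lists follows even where the 3 stage levels are unrelated. The comparison with independent lists therefore does not test a return to the NF52 level. Simulated unchanged groups on shared NF62 arrays gave 0, but with no changed probe hardly any call can be shared, so this 0 does not bear on the reversal. Without the fold limit, 6733 of the 11479 probes that differed at NF62 (58.7%) moved significantly the opposite way by NF66, against 2724 for independent lists. At 2-fold or more the share over both directions was 48.4% (896 of 1852), and 31.6% with quantile normalization of the pancreas channel alone. Over 21406 probes the covariance of the 2 changes was −0.209, and −0.00528 in the simulation, with correlations of −0.686 and −0.506. Both comparisons use the same 3 NF62 arrays. With these divided, so that no array entered both changes, the covariance was −0.203 to −0.183 over 6 divisions. Part of the excess in shared calls can still come from those arrays, and dividing them does not remove the NF62 level that both changes contain.

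**Figure D3:**
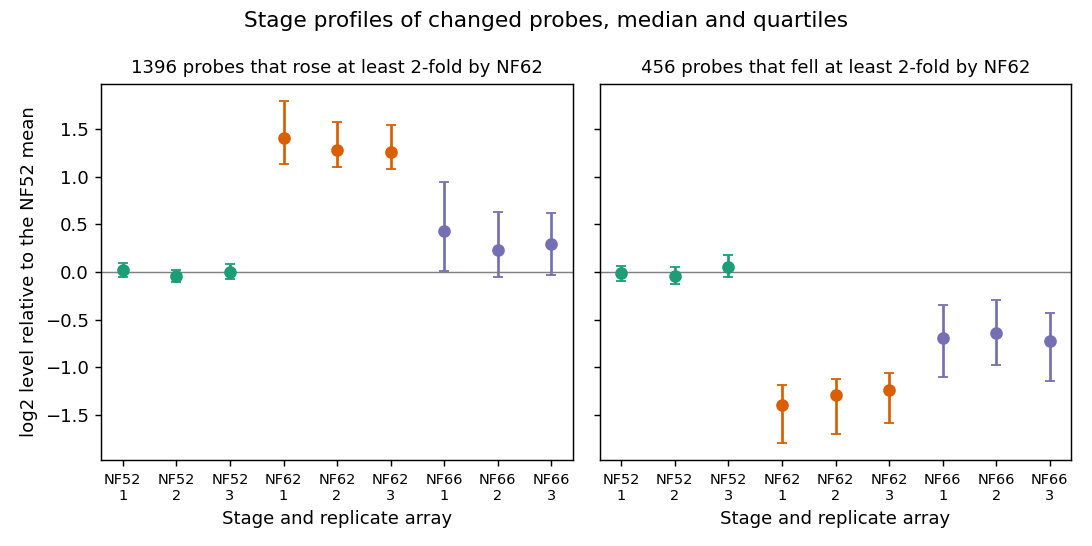
Median log2 level relative to the NF52 mean (y axis) on each of the 9 arrays (x axis, stage and replicate) for the 1396 probes that rose (left) and the 456 that fell (right) at least 2-fold by NF62; bars run from the lower to the upper quartile over probes. The probes were chosen on the NF52 and NF62 arrays shown, and at NF66 the medians lie between the levels of NF52 and NF62 in both sets.

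Rises and falls were also compared for how far they had returned at NF66. The median probe that rose by NF62 kept 23.4% of its change at NF66 (95% bootstrap interval over probes 20.4% to 26.1%), and the median probe that fell kept 50.7% (47.5% to 54.4%). Probes are not independent replicates, so these intervals cover the spread over probes only. With median centring in place of loess the shares were 38.1% and 42.0%, and the 95% bootstrap interval of that gap, −2.07 to 10.1 points, included 0. A change of at least 2-fold from NF62 to NF66 without one of that size before was found in 216 probes that rose and 489 that fell. The 489 had a median log2 change of 0.73 into NF62 (quartiles 0.52 and 0.90) and −1.14 out of it, so their change was not confined to the later step. The 216 late rises had a median log2 change of 1.29, and 132 of them ended at least 2-fold above NF52.

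NF62 was also compared with the mean of NF52 and NF66, a contrast that is orthogonal to the net change from NF52 to NF66. By this measure 1143 probes were at least 2-fold higher at climax and 293 at least 2-fold lower, and 11509 probes passed a limma adjusted p under 0.05 with 5938 higher. Over all 3 stages, 14033 of 21406 probes differed by the moderated F test, 2697 of them with a change of at least 2-fold between some pair of stages. Without background correction 366 probes, 54.9% of them higher, were at least 2-fold different at climax, against 1436 and 79.6%, and over other settings the count across all stages was 773 to 4282.

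From NF52 to NF66, the net difference between the tadpole and the young frog, changes of at least 2-fold were fewer, with 438 probes higher and 243 lower at NF66. The pancreas channel was saturated on all 6 arrays for 7 of these falls and 0 of these rises. Probe CF284427_532 (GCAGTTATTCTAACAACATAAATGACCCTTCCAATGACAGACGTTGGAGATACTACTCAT) was 109-fold higher, from 0.11 ± 0.10 at NF52 through 3.37 ± 1.02 at NF62 to 6.87 ± 0.56 at NF66 (SD, n = 3 each; limma adjusted p = 1.34e-05 for NF66 against NF52). Probe AW765313_402 (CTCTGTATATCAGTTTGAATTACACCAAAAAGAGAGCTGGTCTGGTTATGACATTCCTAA) was 105-fold higher, from −4.44 ± 0.38 through −1.06 ± 0.38 to 2.27 ± 0.20 (limma adjusted p = 3.40e-07). Among the falls, probe BC053824_1058 (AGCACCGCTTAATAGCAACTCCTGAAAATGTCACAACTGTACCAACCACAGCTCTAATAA) was at least 16.4-fold lower over the 27 settings that gave a value and in pancreas signal above background, with log2 ratios of 5.72 ± 0.29 at NF52 and −0.59 ± 0.65 at NF66 (limma adjusted p = 1.01e-05). Probe BC054271_1668 (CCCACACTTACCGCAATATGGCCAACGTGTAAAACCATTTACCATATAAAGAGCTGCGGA) was at least 15.7-fold lower by the same measures, with 5.65 ± 0.19 and 0.07 ± 0.41 (limma adjusted p = 3.12e-06). Both were saturated on all 3 NF52 arrays, which is why only their smallest falls are given. Over other settings that kept all arrays, the log2 changes were 5.81 to 8.97 for CF284427_532 and 4.96 to 7.03 for AW765313_402. In all, 9114 probes differed between NF52 and NF66, 3790 higher and 5324 lower at NF66 (limma adjusted p under 0.05). Of the at least 2-fold changes, 367 of 438 rises and 219 of 243 falls held in direction and threshold under each of 10 normalizations, and 133 and 60 stayed at least 2-fold in all 10. With the pancreas channel alone after loess and Aquantile, 5917 probes differed, without background correction 270 changed at least 2-fold, by the scanner software's log ratio 1191 did, and with median centring 54.9% of all calls were higher at NF66, against 41.6% here.

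**Figure D4:**
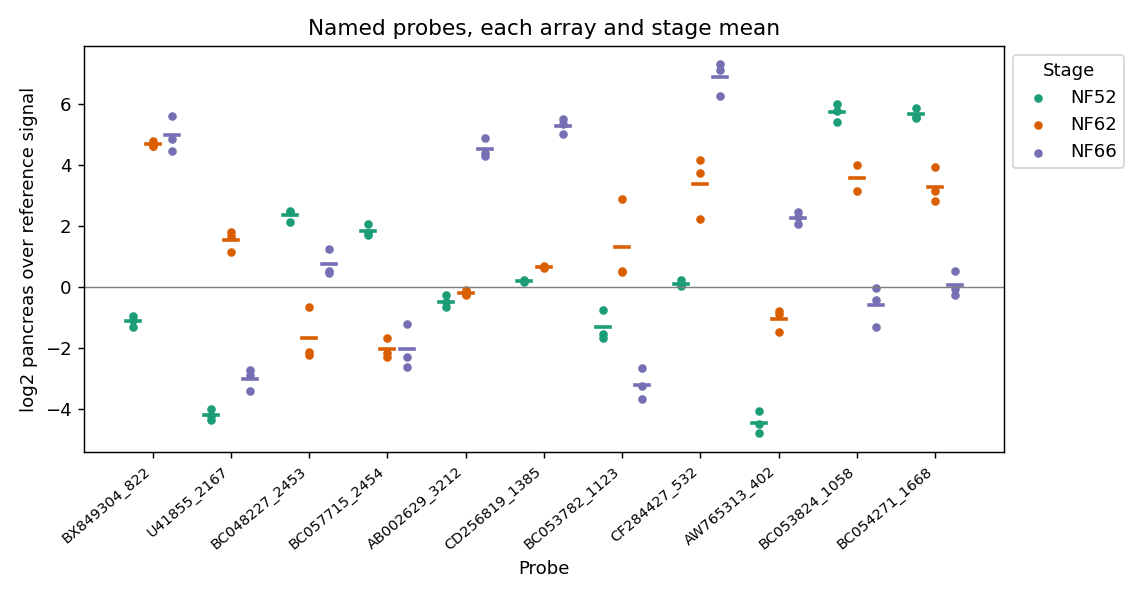
Log2 ratio of pancreas over reference signal (y axis) for each probe named in the text (x axis); points are single arrays, coloured by stage, and horizontal bars are stage means. CF284427_532 climbs at each stage to 6.87 at NF66, U41855_2167 peaks at 1.53 at NF62, and BC053824_1058 and BC054271_1668 fall at each stage, with the NF52 arrays of both saturated.

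A few probes encode a recognisable stretch of protein, and 3 such signatures, fixed before expression values were examined, were found in at least 3 probes and in no reversed or shuffled probe sequence. Homeodomain probes come from transcription factors that bind DNA through a conserved helix. They rose past the threshold at NF62 in 3 of 3 cases, with a median log2 change of 0.76, and 2 of 3 fell past it by NF66. A pair of these carry the same translated stretch, so the group can stand for fewer than 3 genes. Collagen-repeat probes come from the fibrous proteins of the extracellular matrix. At NF62 all 3 were higher, with changes of 0.21 to 0.99, and 2 of 3 passed the threshold. By NF66, 3 of 3 fell past it, with changes of −0.37 to −1.31. Probes of the immunoglobulin variable domain, a part of antibodies and T-cell receptors made by lymphocytes, rose past the threshold in 4 of 6 cases at NF62. At NF66 all 6 were higher than at NF52, by 0.12 to 0.44 with a median of 0.29, and 4 of 6 passed the threshold. Adjusted over the list alone, the counts past the threshold at NF62 were the same, 3, 2 and 4. As sets, the groups passed the self-contained test fry in limma at NF62, with 3 of 3, 2 of 3 and 4 of 6 probes past the threshold singly (adjusted p over 9 tests = 0.000274 for the homeodomain, 0.00101 for collagen and 0.00232 for the immunoglobulin probes). Set against all other probes with limma's camera, none passed (adjusted p = 0.0792, 0.115 and 0.115, and 0.297 for each with an estimated correlation). The homeodomain and immunoglobulin probes were dim, with median signals of 45.9 and 84.6. Over the other settings that kept all arrays, the median change at NF62 stayed above 0 but ranged from 0.15 to 1.75 for the homeodomain, 0.09 to 0.87 for collagen and 0.05 to 0.59 for the immunoglobulin probes.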

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

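The negative control filter, the kept outlier spots, the removal of saturated spots and the count of calls shared by all normalizations were chosen after seeing the data. The changes of named probes kept their direction and significance in 321 recomputed values, 9 of the 12 over 27 settings and 3 over 26. Those 3 (BX849304_822, BC053824_1058 and BC054271_1668) had no value with saturated spots left out. Of the counts of changed probes, 251 recomputed counts stayed within 1.5 times the main count, while 15 did not. Most of the exceptions were counts of at least 2-fold changes. In the order NF62 against NF52, NF66 against NF62, NF66 against NF52, NF62 against both, and any stage, these counts were 516, 414, 270, 366 and 773 without background correction, against 1852, 1614, 681, 1436 and 2697. For NF62 against NF52, NF66 against NF52 and any stage, the scanner log ratio gave 2836, 1191 and 4213, the processed signals 2917, 1202 and 4282, and the deposited values of the series 2840, 1197 and 4223. The pancreas channel after Aquantile gave 5917 for NF66 against NF52 in place of 9114. The share of NF62 changes that turned back by NF66, 58.7%, was 56.3% without background correction, 62.2% with the log ratio, 60.3% with processed signals, 62.5% with median centring, 53.5% with Aquantile, 52.8% with quantile normalization, 62.1% in the value table, 60.4% with the filter on both channels and 57.1% with array weights. At 2-fold or more it was 48.4%, and 34.1%, 39.7%, 42.7%, 35.2%, 38.6%, 31.6% and 39.7% under the first 7 of these. The cause was not tested. Leaving out 1 array gave 53.0% to 61.1% and, at 2-fold, 44.9% to 50.6%, with counts of 10176 to 11487 for NF62 against NF52 and 8835 to 9912 for NF66 against NF62. The percentage of higher calls moved by over 10 points for NF62 against NF52 at 2-fold (75.4% to 49.6% without background correction, 64.8% with the log ratio, 60.6% with quantile normalization, 89.0% with median centring), for NF66 against NF62 (23.0% to 43.2%, 34.8%, 40.1% and 36.5%), for NF62 against both (79.6% to 54.9% without background correction and 66.3% with quantile normalization) and for NF66 against NF52 (64.3% to 51.1% without background correction and 88.9% with median centring). Of the recomputed shares, 38 lay outside the 95% interval of the main value and 66 inside. Of the signature medians, 40 moved by over 0.15 log2 units or changed sign and 194 did not, and none of the called ones changed sign. Of the counts among the 50 brightest probes, 12 moved by over 1.5 times and 40 did not. No scaling moved the median of all probes by over 0.1 log2 units. Most of these settings bring every array to a common centre, so a shift of all probes could hardly appear. With the replicate block the counts were 11134, 9706, 8707, 11183 and 13550, and 10891, 9454 and 8376 probes of the pairwise comparisons were shared with the main calls. Same-numbered arrays deviated together at correlations of -0.21 to 0.247, with 3 of 9 over 0.1. Arrays of different number gave -0.258 to 0.233, with 4 of 18 over 0.1. These values show no clear pairing by number, and with 3 arrays per stage they cannot exclude it. The scan date block was not run, because all arrays shared 1 day, and the gene list alternatives were not run, because no list could be matched to a probe. In the dimmest of 5 equal groups of probes by pancreas signal, 0 changes of at least 2-fold were called at NF62. The groups were formed on the pancreas signal itself and the offset of 50 makes folds of dim probes smaller. This count therefore does not show a limit set by background. Grouped by reference signal, the dimmest group held 21 rises and 6 falls of that size.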

Other observations

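The pairs of probes, the comparison of single arrays with their sisters, the brightest probes, the tests of the stage-specific change and the signal curve of NF62 replicate 1, of GC content and of the dependence of the rise share on normalization, and the interval of the smallest gap between falls and rises were chosen after the results were seen. Pairs of probes for the same accession gave a check within the arrays. Over 96 such pairs the log2 changes correlated at 0.847 from NF52 to NF62, 0.717 from NF62 to NF66 and 0.581 from NF52 to NF66, across probes, which are not independent replicates. Where at least 1 of the pair changed at least 2-fold, both moved the same way in 18 of 19, 22 of 26 and 6 of 7 pairs. Of the 50 probes brightest over all arrays, 11 were saturated on all arrays at NF52, 22 at NF62 and 26 at NF66, so the levels of those probes are capped there. After loess, 32 were called at least 2-fold lower at NF62, and 4 with median centring. With saturated spots left out 9 were called, but there a probe saturated on all arrays of a stage has no value to test. Only 7 of those 32 were lower in raw pancreas signal, and 26 were saturated on some array.

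Other splits of the arrays were counted for each comparison. For each pairwise comparison 1 of 10 splits, the real one, gave as many probes, and 10 splits are too few for a share under 0.05. The real counts were 11479, 10111 and 9114 against at most 0, 1 and 0 in the others, and at 2-fold 1852, 1614 and 681 against at most 0, 1 and 0. For NF62 against both other stages, in a fit of 2 groups, 1 of 84 splits, the real one, reached the real 7278 probes. The highest other gave 5072. At 2-fold the counts were 1317 and 568. A chance split of the arrays is thus unlikely there but not excluded. The other splits include those that set NF52 or NF66 apart, which are stage differences and not chance splits. Run order followed stage, so no split can tell these apart. For the F test, 1 of 100 drawn splits reached 14033, and the highest other gave 5301, with 2697 and 1438 at 2-fold.

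NF62 replicate 1 stood apart from its sisters in 1 direction: 244 probes were at least 2-fold above the mean of replicates 2 and 3 and 3 were below. No other array had over 34 above its sisters. A pool further along the climax change cannot be told apart from other differences: its correlations with the change seen in a sister were low, at 0.12 and 0.20, but those of the sisters were −0.20 to 0.16, and its median changes at climax were the largest of the 3 arrays, 1.37 against 1.26 and 1.22 for probes higher at NF62 and −1.40 against −1.28 and −1.17 for probes lower. At the 244 probes a smooth curve on signal, on values without loess, gave 7.98% of the median difference from the sisters. The 95% bootstrap interval over probes was 7.62% to 8.82%. Those probes were chosen on values after loess, which removes a trend with signal, so a low percentage was largely fixed beforehand. The curve therefore does not decide on dye bias, and dye bias of single probes was not tested. Over all probes, 64 blocks of the slide explained 0.417% of the variance of the difference, which argues against a local defect as its main source. Other tissue in that pool, or a real difference between pools at NF62, stays open and untested, because no probe could be named.

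More probes rose than fell at least 2-fold by NF62, and the data argue against NF62 replicate 1 as the whole cause, since without it the rises made up 75.7%. GC content cannot be told apart from the other sources: the share of rises fell from 88.6% among probes with up to 35% GC to 67.2% at 45% and 44.4% above 45% (40 of 90 changes, 95% binomial interval 34.0% to 55.3%). The excess may depend on the background step, since it was 49.6% without background correction and 60.6% to 89.0% under 8 other settings. A real difference between the stages stays open, untested.

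Falls by NF62 were reversed less than rises by NF66, as a median kept share of 50.7% against 23.4%. The gap was 14.7 points or more in each of 3 groups of like reference signal that held 20 or more of both, which argues against reference signal level there. In the dimmer groups, with only 13 and 6 falls, it was 6.3 and -15 points. Pancreas signal was not matched. For selection on shared arrays, probes were chosen at 2-fold, without a test, on replicate 1 of NF52 and NF62 and measured on the other arrays. There the kept share was a ratio of medians over probes and not the median of single shares. The gap was then 31.4 points (95% bootstrap interval over probes 27.0 to 36.6), which argues against such selection. The choice rests on NF62 replicate 1, the array that stood apart from its sisters. Among 9 other settings the smallest gap was 3.96 points, with median centring, with an interval of -2.07 to 10.1, so an effect of the normalization cannot be told apart from a difference between rises and falls. In the other 8 settings the gap was 14.2 to 29.6 points, and a real difference stays open, untested.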
